A study of Mus musculus with 6 samples.

How the data were processed

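RNA from organoids of mouse colon tumour epithelium was extracted from the gel matrix and made into libraries with a kit for Illumina sequencing, per the labels' protocols. The series holds 6 samples, 3 that received a guide RNA without a target (control) and 3 that received a guide RNA against Atxn1 (knockout), and each was placed in its group by its title. The position and sequence of the guide, and any check of the edit, are not given in the sources used here.

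The authors deposited 1 table of TPM values (transcripts per 1000000 within a library) with 40840 genes, named by RefSeq symbols, and 6 columns. Each column sums to 1000000 and its values are rounded to 2 decimals. Per the file header the table declares 24 samples, while the 6 columns of this series are the ones used. The submitters' processing notes name Trim Galore 0.6.7, cutadapt 3.5, STAR 2.7.7a and 2.7.10a, RSEM 1.3.1 and the genome build GRCm39, with no role or order. The strand setting is not given in the sources used here, so a gene and an overlapping gene on the other strand are not told apart, and near-identical copies can share reads. TPM divides a fixed total among all genes, so a large change of abundant transcripts shifts the others, and it keeps no depth: no counting interval could be given and the depth per sample is unknown. By symbol 0 of the 13 listed protein-coding mitochondrial transcripts were found in the file, so that list was not tested. Whether they stand there under other names is unknown. At most 1 gene per library was listed at 0 while above 20 TPM in all other libraries.

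Values were analysed as log2(TPM + 1), a pseudocount of 1 TPM, which understates the change of low genes. The 12000 genes with a mean of at least 1 TPM over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (moderated test with a mean-variance trend, group as the only term), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Changes are knockout minus control, with standard errors from the same model, and tests are two-sided. A comparison of single values between 3 and 3 libraries by exact permutation cannot go below p = 0.1, so none was used.

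Fixed before the data were examined were the test, its alternatives, the naming rule and 34 gene lists from textbook knowledge of colon epithelium, RAS and Wnt signalling, the Atxn1 and Capicua complex and other cell types. Of these, 29 had at least 5 tested genes. Lists were tested with camera (preset correlation 0.01), which compares a list with all other genes, with adjustment over the 29 lists. None of the 5 calls held with an estimated correlation. With fry, which asks whether the genes of a list move on balance in a single direction, the lowest adjusted p of the 29 lists was 0.122. The symbols of 2 list members were matched through other names. Named genes were Atxn1, Atxn1l and Cic, the 12 largest rises and the 12 largest falls among genes past the threshold with groups apart, at least 5 TPM in the higher group and an assigned symbol, and up to 4 members past the threshold per list, or up to 2 of the highest level where none passed.

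The steps were tested on simulated data for this comparison, with 200 changed genes of 12000. At a log2 change of 1 they recovered 37% of the changed genes and at a log2 change of 2 they recovered 97%, and 6.29% of all calls were false. The shifted list was recovered and 0 unshifted lists were called. This does not show that the calls of real lists, whose genes can vary together, are sound.

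The chromosome of each gene came from a RefSeq table of assembly GRCm38.p6, matched by symbol for 99.5% of tested genes. Because this is not the build named by the submitters, it was used only for which genes share a chromosome or neighbour each other, and no positions are printed. Transcript lengths came from GENCODE annotation of the same assembly and were found for 96.1% of tested genes. Bootstrap intervals of medians are over genes at the 95% level.

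Alternatives were pseudocounts of 0.1 and 0.5 TPM, no filter and a filter at 5 TPM, libraries aligned by median, and quantile normalization. Others were TPM without mitochondrial genes, limma without a trend and with robust estimation, the replicate number as a block, and each library left out. Mitochondrial genes were those whose symbol begins with mt-, and their removal changed little (11998 genes tested, the same 509 calls). Added after seeing the data were the removal of a transcript length trend from each library, the centring of each chromosome, and the omission of chromosomes 12 and 15. Length trend removal and centring also took out the median log2 change of all genes (0.19 before, −0.0017 and −0.0014 after). A centred change is therefore to be set against the earlier change relative to all genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.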

Results

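RNA sequencing was carried out on mouse colon tumour organoids, which are epithelial cultures embedded in a gel matrix. Their cells carry an activating Kras allele and an inactivating Apc allele on a C57BL/6 background. Cas9 was delivered by lentivirus, followed by a guide RNA against Atxn1 (3 knockout libraries) or a guide without a target (3 control libraries). Atxn1 encodes ataxin-1, a nuclear protein that binds the transcriptional repressor Capicua, the product of Cic. The series belongs to a study that searched for genes with a role in tumour progression by transposon insertion in intestinal organoids, and the comparison asks which transcripts differ after Atxn1 is targeted. Levels are TPM (transcripts per 1000000 within a library) as the authors deposited them, and the sequencing depth behind them is unknown because TPM keeps no depth. Each library held 11499 to 12119 genes at 1 TPM or more. Pearson's r of the log2 values across genes was 0.973 to 0.981 between knockout libraries, 0.945 to 0.962 between control libraries and 0.911 to 0.946 between the groups. The first principal component held 52.1% of the variance and parted the groups, and the next held 21.4% and set control replicate 1 apart. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

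The targeted gene was measured first. Atxn1 stood at 2.20 ± 0.734 TPM in the controls and 2.14 ± 0.763 TPM in the knockout libraries (mean ± SD, n = 3 in each group), a log2 change of −0.03 with a standard error of 0.29 (limma adjusted p = 0.964). Its values were 1.56, 3.0 and 2.03 TPM in control replicates 1, 2 and 3, and 3.02, 1.78 and 1.63 TPM in knockout replicates 1, 2 and 3. An insertion or deletion made by Cas9 need not lower a transcript, so this level checks the labels only weakly. Atxn1l, the close relative of Atxn1 that also binds Capicua, was at 8.51 ± 2.92 TPM in controls and 12.5 ± 1.76 TPM in the knockout (n = 3; log2 change 0.54, limma adjusted p = 0.264). Cic itself was at 27.6 ± 10.2 and 28.1 ± 1.92 TPM (n = 3; log2 change 0.08, limma adjusted p = 0.866).

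Some genes went from nearly absent to abundant in the knockout organoids, and others the reverse way. Rhox5, an X-linked homeobox gene, rose from 0.617 ± 0.756 to 615 ± 333 TPM (SD, n = 3). S100a8, a calprotectin subunit already present in the controls, rose from 30.9 ± 23.9 to 575 ± 119 TPM (SD, n = 3). Wfdc2, a secreted protein of the whey acidic protein family, fell from 1311 ± 539 to 0.357 ± 0.232 TPM, and Mmp14, a membrane-type matrix metalloproteinase, from 155 ± 47.9 to 0.01 ± 0.0173 TPM (SD, n = 3). Of 12000 genes tested with limma on log2(TPM + 1), 509 passed an adjusted p of 0.05, 273 higher and 236 lower in the knockout, and 439 of them changed at least 2-fold. Genes with an unadjusted p under 0.05 numbered 2738, where chance gives 600. In all 509 the values of the groups did not overlap, which held for 28.5% of all tested genes against 10% by chance. The median log2 change of all tested genes was 0.19, and other scalings moved the split of calls: 208 higher and 412 lower with medians aligned, 238 and 390 after quantile normalization, and 228 and 399 with a transcript length trend removed. The count depended on single libraries: it was 1484 without control replicate 2, 191 without control replicate 3, and 257, 136 and 135 without knockout replicates 1, 2 and 3.

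The 12 largest rises that met the naming rule were, in order, Rhox5, Bex1, S100a8, Crip1, Ptn, Ifi27l2b, Cav1, Igfbp7, Timp3, Ddah1, Thbs1 and Emid1. Bex1 went from 0.0433 ± 0.0751 to 104 ± 37.5 TPM (SD, n = 3; log2 change 6.61, SE 0.27, limma adjusted p = 1.41e-05). Ptn, which encodes the secreted growth factor pleiotrophin, went from 0.14 ± 0.242 to 19.4 ± 1.08 TPM, and Cav1, the main coat protein of caveolae, from 0.483 ± 0.146 to 16.7 ± 2.14 TPM (SD, n = 3). Thbs1, a matrix glycoprotein, went from 2.81 ± 0.526 to 43.8 ± 26.9 TPM (SD, n = 3). Igfbp7, a secreted binding protein of growth factors, was listed at 0 in all 3 controls and at 13.4, 13.3 and 6.58 TPM in knockout replicates 1, 2 and 3. Ifi27l2b has a near-identical neighbour, Ifi27l2a, so its level is uncertain where reads could be split between them. Among these 12 genes Emid1 alone lost its call in a leave-one-out fit, without control replicate 3 or knockout replicate 3 (highest adjusted p = 0.0934).

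The 12 largest falls were Wfdc2, Mmp14, Snhg9, Ifitm3, Krt36, Urah, Cyp2b10, Fam174b, Unc93b1, Krt83, Dmkn and Krt34. The log2 change was −9.86 for Wfdc2 (SE 0.28, limma adjusted p = 1.98e-06) and −7.23 for Mmp14 (SE 0.25, limma adjusted p = 4.48e-06). Ifitm3, a membrane protein that restricts virus entry, fell from 1478 ± 667 to 65.3 ± 35.7 TPM (SD, n = 3). The keratin Krt36 fell from 256 ± 122 to 13.5 ± 2.62 TPM, and Unc93b1, the escort of endosomal Toll-like receptors, from 17.2 ± 7.84 to 0.25 ± 0.0529 TPM (SD, n = 3). Snhg9, a small nucleolar RNA host gene, was listed at 0 in all 3 knockout libraries and at 27.6, 77.1 and 23.4 TPM in control replicates 1, 2 and 3. Dmkn lost its call without control replicate 3 or any single knockout replicate (highest adjusted p = 0.115). Krt34 lost it without control replicate 1, control replicate 3 or any single knockout replicate (highest adjusted p = 0.167). Its call also ended after each chromosome was centred (limma adjusted p = 0.0767). The log2 change of Krt34 was −3.51 before centring, or −3.69 relative to all genes, and −3.65 after it.

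**Figure D1:**
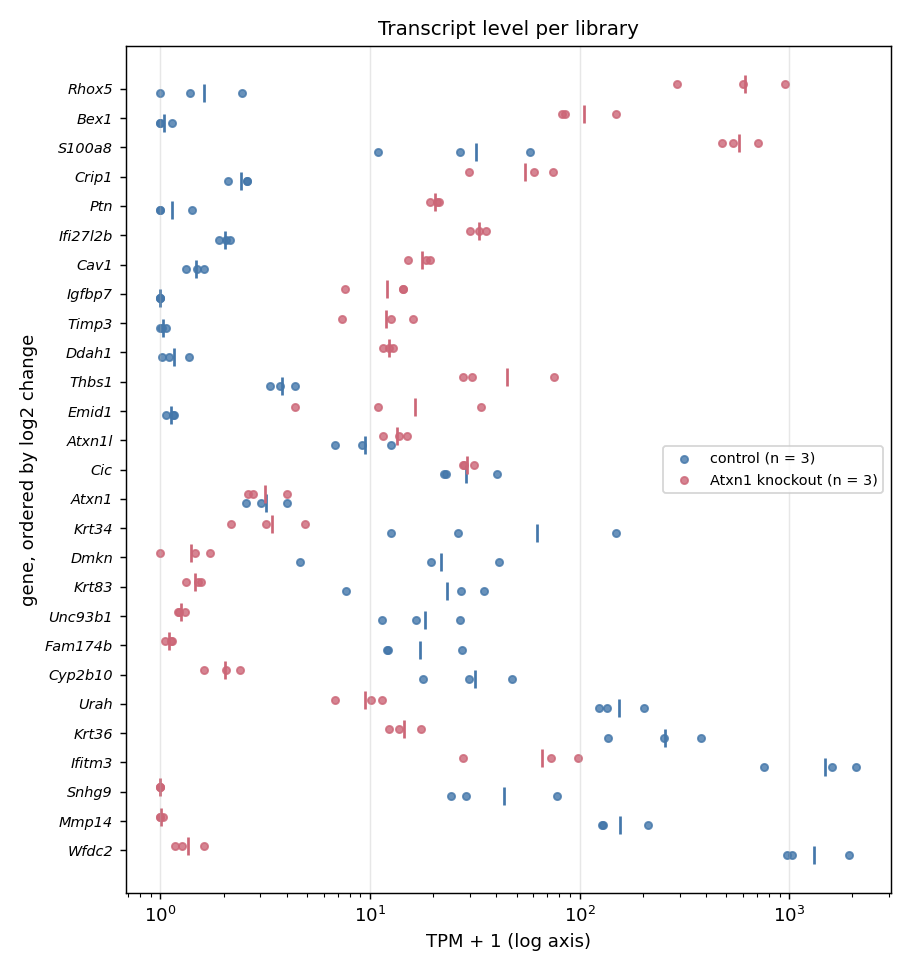
Transcript level of the 24 genes with the largest rises and falls and of Atxn1, Atxn1l and Cic, ordered by log2 change. Points are single libraries on a log axis of TPM + 1 and ticks are group means (n = 3 per group); the groups stand apart for all 24 genes and overlap for Atxn1, Atxn1l and Cic.

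Genes of mitosis and of sterol synthesis stood higher in the knockout as groups. All 20 tested members of the G2/M list had a log2 change above 0, with a median of 0.93 relative to all genes, but 0 of 20 passed singly with limma, over all genes or adjusted over the list alone (11 had an unadjusted p under 0.05). Ube2c, a ubiquitin-conjugating enzyme of mitosis, was at 115 ± 61.7 and 232 ± 36.1 TPM (SD, n = 3; limma adjusted p = 0.0989). Birc5, which encodes survivin, was at 75.4 ± 46.3 and 110 ± 36.4 TPM (SD, n = 3; limma adjusted p = 0.370). The list was called by camera (adjusted p = 3.51e-04), and not with an estimated correlation (adjusted p = 0.752). The libraries overlapped in this measure: the mean log2 level of the list was 3.75, 5.39 and 3.56 in control replicates 1, 2 and 3 and 4.87, 5.77 and 5.54 in knockout replicates 1, 2 and 3. In the sterol synthesis list 20 of 21 members had a log2 change above 0, 2 rose over all genes tested and 16 rose adjusted over the list alone, with a median of 0.58 relative to all genes. Pcsk9, which directs the LDL receptor to degradation, rose from 19.4 ± 8.85 to 58.9 ± 7.47 TPM, and Ldlr, the receptor itself, from 40.3 ± 4.61 to 72.5 ± 12.7 TPM (SD, n = 3). The sterol list was called by camera (adjusted p = 8.97e-05), and not with an estimated correlation (adjusted p = 0.752). The calls of Pcsk9 and Ldlr both ended without control replicate 3, knockout replicate 2 or knockout replicate 3, and that of Ldlr also without control replicate 1 or knockout replicate 1 (highest adjusted p = 0.0994 for Pcsk9 and 0.213 for Ldlr). With each chromosome centred the log2 change of Ldlr was 0.59, from 0.82, and its limma adjusted p 0.0942. Centring also took out the median change of all genes, relative to which Ldlr stood at 0.63 before.

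Of a list that joins markers of fetal or regenerating epithelium with targets of YAP, 5 of 17 tested members fell and 0 rose, over all genes and adjusted over the list alone. The YAP targets Ccn1, Ccn2, Amotl2, Ankrd1 and Ajuba, named after their values were seen, did not pass and went both ways (log2 change 1.15, 0.87, 0.53, −0.37 and −0.22). Ly6a, the Sca-1 antigen, fell from 7932 ± 2089 to 2731 ± 222 TPM (SD, n = 3; log2 change −1.51, SE 0.19, limma adjusted p = 0.00515). Il33, an alarmin cytokine, fell from 155 ± 20.8 to 69.0 ± 18.4 TPM, Tacstd2, the surface antigen Trop2, from 169 ± 46.1 to 78.7 ± 5.77 TPM, and Krt18, a simple-epithelium keratin, from 2522 ± 632 to 1258 ± 92.6 TPM (SD, n = 3). The fifth, Krt7, named after its values were seen, fell from 3527 ± 1302 to 1490 ± 133 TPM (SD, n = 3). The list was called by camera (adjusted p = 3.51e-04), and not with an estimated correlation (adjusted p = 0.752). Its mean log2 level was 8.03, 7.24 and 8.13 in control replicates 1, 2 and 3 and 7.42, 7.31 and 7.57 in knockout replicates 1, 2 and 3. Control replicate 2 thus lay below all 3 knockout libraries. Ly6a, Krt18 and Krt7 lie on chromosome 15, whose genes were lower as a whole. With each chromosome centred their log2 change was −1.12, −0.58 and −0.78, from −1.51, −0.97 and −1.17. Their limma adjusted p was then 0.0626, 0.292 and 0.263. Centring also took out the median change of all genes, relative to which Ly6a and Krt18 stood at −1.70 and −1.16 before. Calls were also lost in leave-one-out fits: for Il33 without control replicate 3, knockout replicate 2 or knockout replicate 3, and for Tacstd2, Krt18 and Krt7 without control replicate 3 or any single knockout replicate (highest adjusted p = 0.102 for Il33, 0.102 for Tacstd2, 0.141 for Krt18 and 0.152 for Krt7).

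Of 6 tested markers of gastric and squamous epithelium, 2 fell over all genes tested and 3 adjusted over the list alone, and all 6 had a log2 change below 0. Sprr1a and Krt13, named after their values were seen, did not pass (320 ± 197 and 278 ± 131 TPM, limma adjusted p = 0.851, and 16.4 ± 7.09 and 13.9 ± 2.85 TPM, limma adjusted p = 0.758; SD, n = 3). Tff1, a gastric trefoil peptide, was listed at 0 in all 3 knockout libraries and at 2.08, 7.66 and 9.10 TPM in control replicates 1, 2 and 3. Krt6a, a squamous keratin on chromosome 15, fell from 13.9 ± 8.30 to 0.86 ± 1.27 TPM (SD, n = 3). With each chromosome centred its log2 change was −2.65, from −3.04, or −3.23 relative to all genes. Its limma adjusted p was then 0.0548. The list was called by camera (adjusted p = 2.29e-04), and not with an estimated correlation (adjusted p = 0.624). With a filter at 5 TPM it kept only 4 members and was not tested. In the list of matrix proteases and invasion genes, 2 of 14 tested members fell and 1 rose over all genes, and 4 fell and 1 rose adjusted over the list alone. Mmp14 and 2 inhibitors of metalloproteinases passed over all genes: Timp1 fell from 6.75 ± 3.57 to 0.64 ± 0.25 TPM and Timp3 rose from 0.0267 ± 0.0306 to 10.97 ± 4.34 TPM (SD, n = 3). The further 2 that fell adjusted over the list alone, named after their values were seen, were the proteases Mmp15 and Adam8 (limma adjusted p over all genes 0.0713 and 0.106). The protease list was called lower by camera (adjusted p = 0.00560), but not with an estimated correlation (adjusted p = 0.624), with medians aligned (adjusted p = 0.0538) or without control replicate 3 (adjusted p = 0.0540). Without control replicate 3 or knockout replicate 2 the calls of Tff1, Krt6a and Timp1 ended, as did those of Tff1 and Timp1 without knockout replicate 3 and that of Krt6a without knockout replicate 1 (highest adjusted p = 0.0717 for Tff1, 0.0840 for Krt6a and 0.102 for Timp1).

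**Figure D2:**
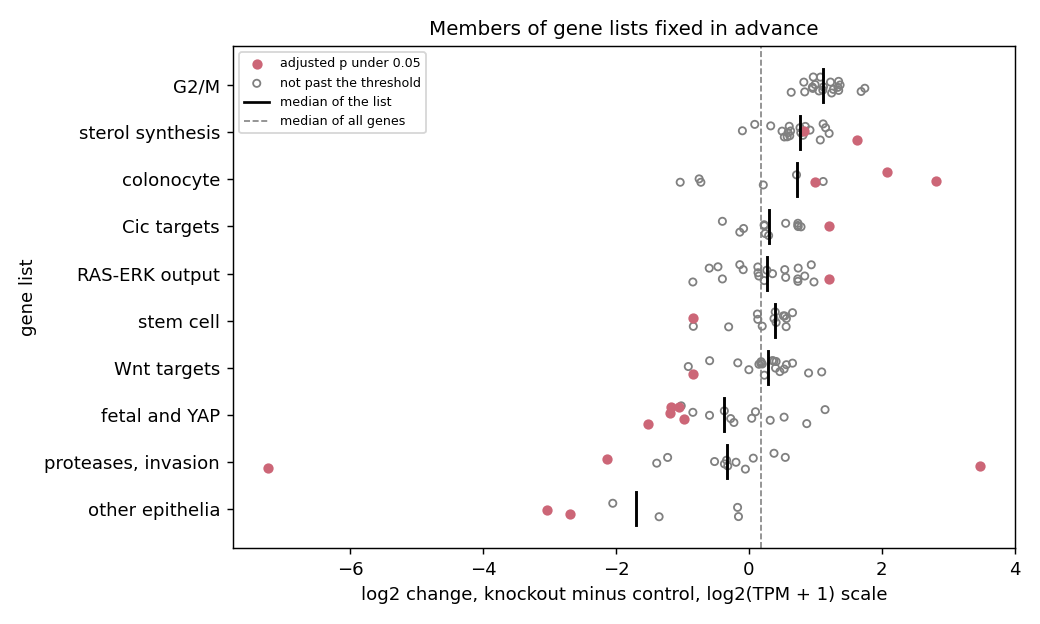
Log2 change, knockout minus control on the log2(TPM + 1) scale, of the tested members of 10 gene lists fixed before the data were examined. Filled points passed an adjusted p of 0.05, bars are list medians and the dashed line is the median of all genes (0.19); all 20 G2/M members lie above 0 and all 6 markers of other epithelia lie below it.

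The lists closest to the known partners of Atxn1 were not called. Of 13 tested genes that Capicua represses, 1 rose and 0 fell (camera adjusted p = 0.354, or 0.810 with an estimated correlation), and the count adjusted over the list alone was also 1. Of 21 tested genes of RAS-ERK output, which shares members with the Capicua list, 1 rose over all genes and 5 adjusted over the list alone (camera adjusted p = 0.460, or 0.752 with an estimated correlation). The gene that rose in both was Spred1, an inhibitor of RAS-ERK signalling, from 18.3 ± 5.74 to 42.1 ± 2.74 TPM (SD, n = 3; log2 change 1.2, limma adjusted p = 0.0311). Its call ended without control replicate 3 or any single knockout replicate (highest adjusted p = 0.142). An unadjusted limma p under 0.05 was found for 3 of the 13 Capicua genes and 8 of the 21 RAS-ERK genes. Relative to all genes the medians of these lists were 0.11 and 0.08. In the simulated data only 37% of genes with a log2 change of 1 were recovered, so rises of that size can be missed. Of the Wnt targets 1 of 20 fell and of the stem cell markers 1 of 14 (camera adjusted p = 0.909 and 0.926). It was the same gene, Ephb3, a receptor that positions cells along the crypt, which fell from 28.9 ± 3.89 to 15.7 ± 1.36 TPM (SD, n = 3; limma adjusted p = 0.0451) and lost its call without control replicate 3 or any single knockout replicate (highest adjusted p = 0.212). Adjusted over the list alone, 2 Wnt targets and 1 stem cell marker fell.

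Single markers of differentiated epithelium changed while their lists were not called. Of 9 tested colonocyte markers 3 rose: Ces2e, a carboxylesterase, from 1.17 ± 0.556 to 15.8 ± 9.51 TPM, and the brush border cadherins Cdhr2, from 9.03 ± 7.70 to 35.1 ± 8.02 TPM, and Cdhr5, from 15.2 ± 2.47 to 31.5 ± 6.52 TPM (SD, n = 3; camera adjusted p = 0.460). Adjusted over the list alone, 4 rose and 1 fell. Among epithelial identity and junction genes 2 of 20 rose and 1, Krt18, fell (camera adjusted p = 0.460; 2 rose and 3 fell adjusted over the list alone). The risen members were Hnf4a, a transcription factor of intestinal epithelium, from 11.3 ± 5.82 to 50.1 ± 7.97 TPM, and Cldn2, a tight junction channel protein, from 2.63 ± 1.86 to 16.4 ± 9.96 TPM (SD, n = 3). Of 8 goblet cell markers 1 rose, the transcription factor Creb3l1 (0.04 ± 0.0693 to 2.65 ± 1.495 TPM; camera adjusted p = 0.368), and adjusted over the list alone 1 rose and 2 fell. Of 6 tuft cell markers 1 fell, the actin-binding protein gene Avil (70.9 ± 70.7 to 6.25 ± 1.55 TPM; camera adjusted p = 0.162), and adjusted over the list alone 1 rose and 1 fell. All 7 of these calls other than Krt18 ended in leave-one-out fits: Cdhr2, Cdhr5, Ces2e, Cldn2, Creb3l1 and Avil without control replicate 3, and Hnf4a without knockout replicates 2 or 3, with highest adjusted p values from 0.0608 for Ces2e to 0.209 for Cdhr5. Further losses were those of Cdhr2, Cdhr5, Cldn2 and Avil without any single knockout replicate, Ces2e without knockout replicate 2, Creb3l1 without knockout replicate 3, Cdhr5 and Cldn2 without control replicate 1 and Cdhr2 without control replicate 2. With each chromosome centred the log2 change of Cdhr2, Cdhr5, Cldn2 and Creb3l1 was 1.76, 0.870, 1.91 and 1.45, from 2.09, 0.998, 2.23 and 1.74. The limma adjusted p was then 0.0986, 0.0532, 0.0772 and 0.0700. Centring also took out the median change of all genes, relative to which these genes stood at 1.90, 0.809, 2.04 and 1.55 before. Of Paneth and deep crypt secretory markers 3 were tested and 0 passed with limma (1 had an unadjusted p under 0.05). Among them was Nupr1 (2748 ± 3006 and 487 ± 78.3 TPM, limma adjusted p = 0.151). Its control mean rests largely on control replicate 1, with 6192, 651 and 1403 TPM in control replicates 1, 2 and 3. The 1 enteroendocrine marker tested, Cpe, was at 207 ± 37.9 and 153 ± 33.3 TPM (limma adjusted p = 0.2498).

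None of the 13 further signalling, stress and metabolism lists was called by camera with the main settings, though other settings called some. In Notch targets 1 of 9 rose, the ligand Jag1, from 6.93 ± 2.97 to 21.1 ± 3.99 TPM (SD, n = 3; camera adjusted p = 0.460; 1 rose adjusted over the list alone). In antigen presentation 1 of 11 rose, B2m, the light chain of class I molecules, from 74.8 ± 19.3 to 190 ± 35.1 TPM (SD, n = 3; camera adjusted p = 0.529; 1 rose adjusted over the list alone). In the xenobiotic list 1 of 17 rose, the retinal dehydrogenase Aldh1a1, from 168 ± 27.9 to 361 ± 27.2 TPM (SD, n = 3; camera adjusted p = 0.254; 1 rose and 2 fell adjusted over the list alone). Of p53 targets 1 of 19 rose, Perp (camera adjusted p = 0.529; 3 rose and 1 fell adjusted over the list alone), and of the integrated stress and unfolded protein response 1 of 20, Manf (camera adjusted p = 0.460; 2 rose adjusted over the list alone). In the PPAR list 2 of 13 fell, Angptl4, an inhibitor of lipoprotein lipase, from 3.11 ± 1.37 to 0.02 ± 0.0346 TPM, and Acot1 (camera adjusted p = 0.648), and 2 rose and 2 fell adjusted over the list alone. Immediate early and heat shock genes went both ways, with Dusp1 lower and Hspa1a higher among 17 (camera adjusted p = 0.0777), and 1 rose and 3 fell adjusted over the list alone. In hypoxia and glycolysis 1 of 21 fell, Ndrg1, from 153 ± 73.9 to 48.1 ± 7.77 TPM (camera adjusted p = 0.0633), and of NF-kB targets 1 of 16, Tnfaip2 (camera adjusted p = 0.335), and in each of these lists 1 rose and 1 fell adjusted over the list alone. Ndrg1 lies on chromosome 15 and Acot1 and Tnfaip2 on chromosome 12. With each chromosome centred their log2 change was −1.15, −1.92 and −1.09, from −1.54, −2.25 and −1.42, or −1.73, −2.44 and −1.61 relative to all genes. Their limma adjusted p was then 0.129, 0.0514 and 0.0907. In the Hedgehog, BMP and TGF-beta list 0 of 11 passed over all genes with limma (8 had an unadjusted p under 0.05), and 6 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0779). In the interferon (15 tested), G1/S (20 tested) and mesenchymal (5 tested) lists 0 passed with limma, over all genes or adjusted over the list alone, while 5, 2 and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.355, 0.276 and 0.247). In the Wnt, interferon, NF-kB and PPAR lists the median lay above that of all genes while camera ranked the list lower, and in the ribosomal protein list it lay below while camera ranked it higher, with none of these called. The calls of these 11 genes ended in leave-one-out fits. The replicates whose omission ended them were control replicate 3 (all but Aldh1a1 and Ndrg1), knockout replicate 1 (all but Aldh1a1, Angptl4 and Hspa1a), knockout replicate 2 (all but Aldh1a1), knockout replicate 3 (all but Hspa1a), control replicate 1 (Manf) and control replicate 2 (Ndrg1), with highest adjusted p values from 0.0602 for Aldh1a1 to 0.208 for Manf. With each chromosome centred the log2 change of Aldh1a1, B2m, Perp and Manf was 0.71, 1.07, 0.60 and 0.44, from 1.11, 1.35, 0.80 and 0.68. The limma adjusted p was then 0.104, 0.0791, 0.136 and 0.176. Centring also took out the median change of all genes, relative to which these genes stood at 0.92, 1.16, 0.61 and 0.49 before.

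The lists that other settings called were these, all with camera's preset correlation. With an estimated correlation, run with the main settings only, 0 lists were called, and the adjusted p was 0.624 for the immediate early list, 0.752 for the Hedgehog, hypoxia and goblet cell lists, 0.810 for the xenobiotic list and 0.835 for the G1/S and stress response lists. The Hedgehog, BMP and TGF-beta list was called higher after quantile normalization (adjusted p = 0.0335), with the length trend removed (0.0207), with each chromosome centred (0.0489) and with the replicate number as a block (0.0433). It was also called without control replicate 3 (0.0495), knockout replicate 2 (0.0270) or knockout replicate 3 (0.0424). The hypoxia and glycolysis list was called lower with a filter at 5 TPM (adjusted p = 0.0226), without chromosomes 12 and 15 (0.0295), and without control replicate 1 (2.24e-04), knockout replicate 1 (0.0396) or knockout replicate 2 (0.0270). The immediate early list was called lower with a filter at 5 TPM (adjusted p = 0.0147), without control replicate 2 (0.0147) and without knockout replicate 1 (0.0396). The xenobiotic list was called lower without control replicate 2 (adjusted p = 0.0352) or knockout replicate 3 (0.0311). The G1/S list was called higher without control replicate 2 (0.00106) or knockout replicate 1 (0.0347), the stress response list higher without control replicate 1 (7.87e-04) and the goblet cell list lower without knockout replicate 2 (0.0172).

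Other settings with all 6 libraries also ended calls of single genes. Without a filter on low values, which tests more genes, those of Acot1, Avil, B2m, Cdhr2, Cdhr5, Ces2e, Cldn2, Dmkn, Dusp1, Emid1, Ephb3, Hnf4a, Il33, Jag1, Krt6a, Krt7, Krt18, Krt34, Ldlr, Manf, Ndrg1, Pcsk9, Perp, Spred1, Tacstd2, Timp1 and Tnfaip2 ended (adjusted p from 0.0509 for Ces2e to 0.125 for Krt7). With a filter at 5 TPM those of Cdhr2, Cdhr5, Cldn2, Krt7, Krt34, Ldlr, Manf, Ndrg1 and Perp ended (0.0502 for Ndrg1 to 0.0573 for Ldlr). With medians aligned those of Aldh1a1, Cdhr2, Cldn2, Krt7, Krt34, Ldlr, Manf and Perp ended (0.0520 for Cldn2 to 0.139 for Manf). After quantile normalization those of Cdhr2, Cldn2, Krt7, Krt18 and Krt34 ended (0.0527 for Krt34 to 0.0791 for Krt7). With limma run without a trend those of Cdhr2, Cdhr5, Ephb3, Krt7, Krt18, Krt34, Ldlr, Manf, Ndrg1 and Perp ended (0.0504 for Ephb3 to 0.0854 for Manf), and with robust limma those of Cdhr2 (0.0502) and Krt34 (0.0672). With the replicate number as a block those of Cdhr5, Ephb3, Ldlr and Manf ended (0.0579 for Manf to 0.0858 for Ephb3). With the length trend removed, chosen after seeing the data, those of Cdhr2, Krt7, Krt34, Ldlr and Perp ended (0.0523 for Krt7 to 0.0928 for Ldlr), and without chromosomes 12 and 15, chosen likewise, that of Ldlr (0.0510).

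No gene of the control lists passed. Of 25 ribosomal protein genes and 24 nuclear-encoded genes of oxidative phosphorylation 0 passed with limma, over all genes or adjusted over the list alone, and 2 and 5 had an unadjusted p under 0.05 (camera adjusted p = 0.460 and 0.127). Of the replication histones 0 of 9 passed with limma, and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.214). With quantile normalization the ribosomal protein and oxidative phosphorylation lists were both called higher with the preset correlation (adjusted p = 0.00313 for each). With an estimated correlation and the main settings neither was (adjusted p = 0.835 and 0.810). The ribosomal protein list was also called higher without control replicate 1 (adjusted p = 0.0178), and the oxidative phosphorylation list higher without a filter (adjusted p = 0.0471). Transcripts of fibroblasts were under the filter (0 of 17 tested), as were all leukocyte and endothelial markers except Cd68 and Vwf. Cd68 was at 28.1 ± 15.03 and 10.6 ± 3.44 TPM and Vwf at 1.52 ± 0.468 and 0.85 ± 0.295 TPM (SD, n = 3; limma adjusted p = 0.140 and 0.357), and 1 of these 2 was lower adjusted over the list alone.

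Genes of chromosomes 12 and 15 were lower in the knockout as a whole. Relative to all genes the median log2 change was −0.50 on chromosome 12 (95% bootstrap interval −0.55 to −0.47, 437 genes) and −0.55 on chromosome 15 (−0.60 to −0.51, 496 genes), and lay between −0.07 and 0.26 on the other chromosomes. Chromosomes 12 and 15 carried 88 of the 236 lower genes, or 37.3%, against 7.78% of all tested genes (odds ratio 7.68, Fisher's exact test, two-sided p = 2.53e-38). The genes are not independent and the chromosomes were picked after seeing these data, so this p-value is descriptive only. Relative to the mean of all libraries, the median of chromosome 15 was 0.25, 0.28 and 0.35 in control replicates 1, 2 and 3 and −0.28, −0.28 and −0.30 in knockout replicates 1, 2 and 3. Chromosomes 1 and 19 shifted up the most, with medians relative to all genes of 0.26 (0.22 to 0.30) and 0.21 (0.16 to 0.24). On both, the medians of all 3 knockout libraries lay above those of all 3 controls. Leaving out chromosomes 12 and 15 does not remove these shifts. Without the genes of chromosomes 12 and 15, tested as an alternative chosen after seeing the data, 387 genes passed, 246 higher and 141 lower. With each chromosome centred, chosen likewise, 363 passed, 164 higher and 199 lower. Centring also took out the median log2 change of all genes (0.19), which can itself move the split of calls.

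**Figure D3:**
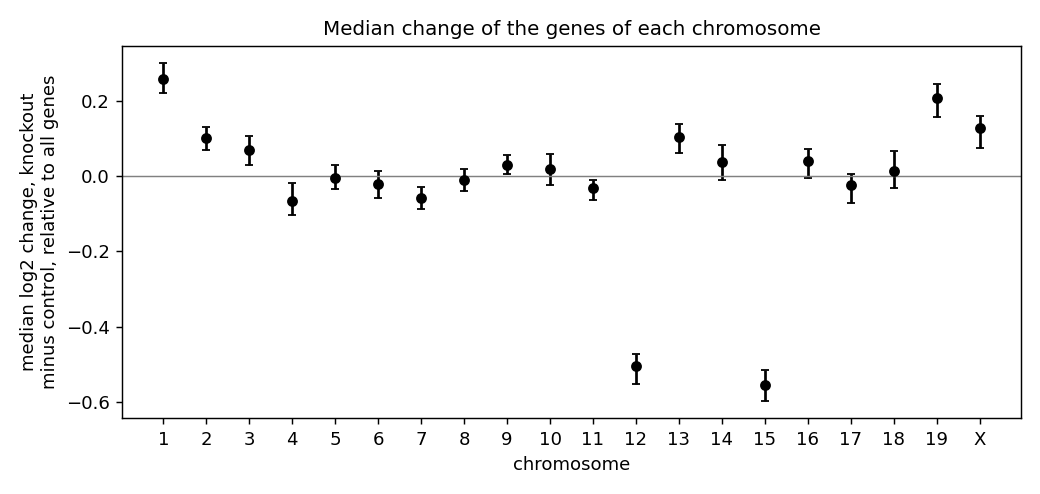
Median log2 change, knockout minus control and relative to all genes, of the tested genes of each chromosome, with 95% bootstrap intervals over genes. Chromosome 12 (−0.50) and chromosome 15 (−0.55) lie apart from all others, which range from −0.07 to 0.26. Chromosomes 1 (0.26) and 19 (0.21) lie highest.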

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

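The length trend removal, the chromosome centring and the omission of chromosomes 12 and 15 were chosen after seeing the data; all others were fixed before. Of the 53 named genes past the threshold 0 changed direction under any setting, 24 kept their call in every setting with all 6 libraries that gave them a value, 21 in every setting that did, and 31 lost it without at least 1 library. Over all settings and named genes other than Atxn1, 1209 of 1425 values kept their direction and side of the threshold. Of the rest, 192 lost the call, 8 gained it and 16 turned direction. Atxn1, left out of these counts, turned direction without control replicate 2, knockout replicate 2 or knockout replicate 3. Depth is unknown, so its part cannot be given. Tests for count data, planned only for counts, were not run because the table holds TPM. No value exists with the 5 TPM filter for Atxn1, Angptl4, Creb3l1, Hspa1a, Tff1, Timp1, Vwf and the other-epithelia, goblet, tuft, mesenchymal and histone lists, nor without knockout replicate 2 for Creb3l1. Nor does one exist with the length trend removed for H1f2, H2bc4 and the histone list, without knockout replicate 1 for the mesenchymal list, or without chromosomes 12 and 15 for the mesenchymal list and Acot1, Cox6c, Crip1, Ifi27l2b, Krt6a, Krt18, Krt83, Ly6a, Ndrg1 and Tnfaip2.

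The 509 changed genes (273 higher, 236 lower) became 265 (123 higher, 142 lower) with a filter at 5 TPM, which tests fewer genes. Without 1 library the count ranged from 135 to 1484, with 76 to 1174 higher and 54 to 310 lower. Lower genes numbered 136 without a filter, 412 with medians aligned, 390 after quantile normalization, 399 with the length trend removed and 141 without chromosomes 12 and 15, where fewer genes are tested. Higher genes numbered 164 with chromosomes centred, which also took out the median change of all genes. Other causes were not tested.

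Camera called 5 lists, 4 with medians aligned, 8 after quantile normalization, 5 to 8 without 1 library and 0 with an estimated correlation. It called 6 without a filter, with a filter at 5 TPM, with the replicate block, with the length trend removed, with chromosomes centred and without chromosomes 12 and 15. With the 5 TPM filter the other-epithelia list kept too few members (4) to be tested. With that correlation the adjusted p was 0.624 for the protease and other-epithelia lists and 0.752 for the fetal, G2/M and sterol lists. The protease list had 0.0538 with medians aligned and 0.000896 to 0.0540 without 1 library, the highest without control replicate 3. The cause was not tested.

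Values that turned direction belonged to genes that did not pass with the main settings. Atxn1 ranged from −0.22 to 0.15 without 1 library. Cic was −0.14 with medians aligned, −0.094 after quantile normalization, −0.18 with the length trend removed, −0.050 with chromosomes centred and −0.068 to 0.35 without 1 library. With medians aligned and with chromosomes centred, Cox4i1 was −0.078 and −0.048, Rpl32 −0.062 and −0.039, and Rplp1 −0.025 and −0.045. Cox6c was 0.024 with chromosomes centred, and Mmp7 ranged from −0.88 to 0.22 without 1 library. The cause was not tested.

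The replicate number as a block gave 546 changed genes and 6 called lists. Deviations from the group means correlated across genes by −0.24, 0.31 and −0.22 between libraries numbered 1, 2 and 3. Not every sample correlated best with its own number, but 3 libraries per group cannot settle whether the numbers pair the samples.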

Other observations

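Both gene families, and the tests of copy number, of the guide against the line, of other cell types, of a released repressor and of a segment at single switched genes, were chosen only after the results were seen; the other tests were written before theirs.

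Keratins were counted as a family because several stood among the largest falls. Of the 23 tested keratin genes counted here 0 rose and 7 fell (Krt7, Krt18, Krt34, Krt36, Krt79, Krt83 and Krt84), with a median log2 change of −0.97. Krt6a, on chromosome 15, was tested and also fell (log2 change −3.04, limma adjusted p = 0.0195). It is left out of all counts and medians in this paragraph. Krt84 fell from 12.8 ± 8.74 to 0.657 ± 0.272 TPM and Krt79 from 11.9 ± 4.73 to 2.17 ± 0.86 TPM (SD, n = 3; limma adjusted p = 0.0138 and 0.0148, or 0.0551 and 0.0550 without a filter). Krt19, the most abundant, was at 6618 ± 2009 and 3667 ± 423 TPM and did not pass (limma adjusted p = 0.0937). On chromosome 15 lie 11 of the 23. With each chromosome centred 4 of the 23 fell and the median was −0.95. Centring also took out the median change of all genes, relative to which the keratin median was −1.16 with medians aligned. For the 11 on chromosome 15 the median was −1.17 before and −0.78 after centring. Of the 12 keratins elsewhere 2 fell before and 1 after centring (medians −0.83 and −0.98). Without control replicate 1, 2 or 3 the number of counted keratins that fell, Krt6a left out, was 7, 11 and 4. Without knockout replicate 1, 2 or 3 it was 3, 2 and 3. Aligned medians, quantile normalization and length trend removal left 0 of the 23 risen and 5, 4 and 5 fallen. The medians were −1.19, −1.08 and −1.10.

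In the Ly6 family of surface proteins, chosen likewise, 7 of 11 tested genes fell and 0 rose, with a median log2 change of −1.51. Beside Ly6a these were Ly6c1, Ly6d, Ly6e, Ly6g, Ly6g6c and Ly6g6e. Ly6g fell from 2629 ± 417 to 805 ± 83.8 TPM and Ly6d from 841 ± 664 to 71.7 ± 30.2 TPM (SD, n = 3; limma adjusted p = 0.00129 and 0.0104). Ly6g6e, on chromosome 17, fell from 19.9 ± 3.18 to 3.55 ± 0.432 TPM (SD, n = 3; limma adjusted p = 0.00182). On chromosome 15 lie 8 of the 11, and with each chromosome centred 5 fell and the median was −1.12. Relative to all genes, whose median change centring also took out, the family median was −1.70 with medians aligned. Without 1 library 5 to 9 fell, and 6, 7 and 7 with medians aligned, after quantile normalization and with the length trend removed. Close copies such as Ly6c1 and Ly6c2 can share reads, so single levels are uncertain.

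Genes of chromosomes 12 and 15 were lower in all 3 knockout libraries than in all 3 controls. A transcript length trend is argued against as the cause, because with it removed from each library the higher of both medians was still −0.52. A copy number difference of whole chromosomes remains a candidate explanation. All 8 consecutive blocks of genes, 4 per chromosome, had medians between −0.61 and −0.37, which does not tell it from another chromosome-wide cause. In 0 of 10000 shuffles of genes was a chromosome median as low. The chromosomes were picked by these medians and shuffles treat genes as independent, so the shuffles do not bear on the cause. Whether a copy number difference came with the Atxn1 guide or separated the lines beforehand cannot be told apart. The column names share 1 stem per guide, and the labels do not say whether a stem stands for a line. As DNA was not measured, copy number is a hypothesis.

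A set of 22 genes was at 5 TPM or more in all libraries of one group and under 1 TPM in all of the other, 14 gained and 8 lost in the knockout and 2 on chromosome 12 or 15, where the other 9 splits of the 6 libraries gave at most 1. A gained or lost segment shifting its neighbours by 0.5 or more, a cutoff chosen here, is argued against for the set as a whole. The 88 nearest tested genes had a median shift in the same direction of 0.18 (95% bootstrap interval 0.08 to 0.27). A segment with a smaller shift, or one that ends before these genes, stays open. A segment also stays open for Krt83, Repin1 and Timp3, whose own neighbours had medians of 1.44, 0.69 and 0.53. All 4 neighbours of Krt83 are keratins, and at Repin1 and Timp3 only 3 of 4 shifted with the gene. At Igfbp7, Mmp14, Unc93b1 and Cav1 all 4 neighbours shifted with the gene, by medians of 0.39, 0.39, 0.27 and 0.14. A segment stays open there too. Fibroblasts, leukocytes or endothelium in 1 group are argued against by their abundant transcripts, none of 8 above 0.42 TPM in a group mean. Of the set 63.6% was gained (exact 95% interval 40.7% to 82.8%, which treats genes as independent). Direct release from repression by ataxin-1 and Capicua would raise genes, so it leaves the 8 lost ones unexplained. Whether these fell as a later consequence of such release was not tested. Loss of single genes, a lasting difference in gene silencing between lines and an effect of the knockout on part of the set stay open and untested.

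The G2/M and sterol synthesis lists were higher in the knockout with camera's preset correlation, though not with an estimated one. At camera's preset correlation a transcript length trend as the whole cause is argued against by the fits with it removed (adjusted p = 1.32e-05 for both lists). With an estimated correlation the fits without the trend were not run. Expression level and length shared with other genes are argued against as the whole cause by 10000 matched random lists, since both medians lay at percentile 100. For G2/M the median was 1.12 against a range of 0.04 to 0.40 that held 95% of random medians, and for sterol synthesis 0.77 against −0.05 to 0.28. Both lists were picked by their calls in these data, and random genes were drawn singly although list genes can vary together. The percentile is thus no measure of chance. In leave-one-out fits at camera's preset correlation the adjusted p was at most 0.0178 for G2/M and 3.41e-04 for sterol synthesis. These fits cannot exclude a single library as the cause, because with an estimated correlation neither list was called with all 6 libraries (adjusted p = 0.752). The mean log2 level of the sterol list was 5.58, 6.25 and 5.80 in control replicates 1, 2 and 3. It was 6.46, 6.73 and 6.66 in knockout replicates 1, 2 and 3, above all 3 controls. A difference in growth state at harvest, such as density or time since passage, and an effect of Atxn1 loss stay open and untested, and control replicate 2 lay above knockout replicate 1 in the G2/M mean (5.39 against 4.87).

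Of the 10 splits of the 6 libraries into 3 and 3, only the real one, 1 split, gave as many as its 509 changed genes, and the highest of the others gave 1. With 10 splits the share cannot go under 0.05.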
